A study of Homo sapiens with 6 samples.

How the data were processed

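The series holds RNA sequencing of the human leukaemia line MOLM-13 after 20 h in 5 µM DB2115 or in vehicle (0.001% DMSO). Per the labels' protocols, cells grew in RPMI medium with 10% serum, and 1.0 µg of total RNA per library went to a commercial sequencing service, whose method of selecting messenger RNA is not given in the sources used here. The submitters' processing notes name FastQC, STAR, DESeq2 and build hg38, with no versions. Aligner settings, annotation, counting tool and strandedness are not given in the sources used here, so reads of overlapping, antisense or near-identical genes such as NCF1 cannot be assigned with certainty. The deposited table gives raw read counts per gene, not normalised by the authors, for 58381 versioned Ensembl gene identifiers in 6 columns. Of these identifiers 58261 received a symbol, and coordinates were taken from GENCODE release 29 on GRCh38, which holds 58216 of them.

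The labels list 3 libraries per group, but the columns carry only letters. The third column equalled the sum of the other two exactly in 85.6% (vehicle) and 86.3% (DB2115) of genes with counts, and the totals had ratios of 1.002 in both groups. It was therefore treated as a pooled column and left out, and 4 libraries, 2 per group, were analysed. The plan written before the data were examined assumed 6 independent libraries, and a fit of all 6 columns was kept as an alternative. The remaining columns of a group differed from each other beyond sampling noise, with a median chi-square per gene of 1.77 (vehicle) and 2.55 (DB2115) against 0.455 for sampling alone. Total counts ran from 36547900 to 42446253, so 3 counts in 1 library correspond to between 0.0707 and 0.0821 CPM.

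Counts were scaled by TMM and filtered with filterByExpr (minimum count 10, minimum total 15), which left 17219 genes. The DB2115 and vehicle groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with treatment as the only term and Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 6.33%. Levels are CPM after TMM scaling, as mean ± SD. Standard errors were obtained from the fold change and its F value, which tests against no change. For large changes with few counts in 1 group they fall below counting error and are too small. Fold changes against a group without counts are bounds against 3 counts over the group. Genes with 1 to 3 counts, H19 and TASL have a ratio with an exact 95% counting interval.

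Before the data were examined, 28 gene lists were written from general knowledge: PU.1 targets, monocyte, granulocyte and other lineage markers, myeloid factors, the MLL-AF9 programme, growth, cell cycle, stress, immune and metabolic pathways. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as alternatives. Whereas camera compares a list with other genes, fry tests it against no change. List members below the filter were not tested, and a member silent in vehicle could pass the filter only by rising. Named genes were SPI1, CSF1R, ITGAM and CEBPE, the 6 largest rises and falls with a mean of at least 5 CPM and no overlap between groups, and up to 3 members with the smallest adjusted p per called list. A gene selected by this rule is not reported here. With 2 libraries against 2, chance alone separates the groups in 33.3% of genes, counting both directions. Other list members and the genes of the closing section were chosen as examples after their values were seen. Shares of counts were compared by exact permutation tests in scipy 1.17.1.

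The fit was tested on simulated counts for the same 17219 genes in 2 against 2 libraries with 50 genes changed at each fold. It recovered 58%, 66%, 86% and 100% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, and 17 of 172 calls were false. Alternatives covered other scaling factors, filters and thresholds, DESeq2 1.42.0, limma-voom, each library left out in turn and, added after seeing the data, the 6-column fit, a fit without mitochondrial genes and a block on the column letters. Transcript GC content and length were taken from GENCODE transcripts, and their trend with fold change was fitted by loess.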

Results

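RNA sequencing was used to compare MOLM-13 cells kept for 20 h in 5 µM DB2115 with cells kept in vehicle, 0.001% DMSO. MOLM-13 is an established line of human acute myeloid leukaemia that carries an MLL-AF9 fusion and an internal tandem duplication in FLT3. The sample titles give DB2115 only by this code name. The plan written before the data were examined treated it as a diamidine, a class of AT-rich DNA binders. It included the mitochondrial share of counts partly for that reason. The series title names PU.1, the ETS-family transcription factor encoded by SPI1, so the contrast asks how transcription in a PU.1-expressing leukaemia line responded to the compound. The deposited count table holds 3 columns per group, and the third column of each group was the sum of the other two within 1% in 98.5% of the genes with at least 200 counts. That column was therefore not an independent library, and all comparisons below rest on n = 2 libraries per group. Total counts were 36547900 and 42446253 in the vehicle libraries and 40067286 and 39647758 in the DB2115 libraries. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

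DB2115 was followed by a broad change of the transcriptome, with PU.1 target genes and monocyte and macrophage markers mostly higher and MYC and its ribosome biogenesis targets lower. Of 17219 genes tested, 5634 rose and 5396 fell, and 3009 rose and 1641 fell at least 2-fold. The largest fitted rises among genes with a mean of at least 5 CPM included KRT80, a type II keratin, and SIGLEC1, the macrophage receptor sialoadhesin, neither of which had a count in vehicle. The largest falls included MYC, from 554 ± 15 to 21.8 ± 3.46 CPM (SD, n = 2), and RGS18, a regulator of G-protein signalling in blood cells. Calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. The count of genes changed at least 2-fold was 2540 in place of 4650 when 1 CPM in 3 libraries was required, a filter that leaves out genes silent in 1 group. The split between rises and falls depended on the scaling, with 6298 higher and 4699 lower under upper-quartile factors. TMM scaling takes most genes as unchanged, whereas 64.1% were called here. All rises and falls are therefore relative to the RNA sequenced, and a change in RNA per cell would not be seen. Small shifts in particular depend on the scaling.

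Among the 6 largest rises by fitted fold change, an order that depends on edgeR's prior count for genes without vehicle counts, KRT80 (chromosome 12, 52168996 to 52192000) went from 0 counts in vehicle to 22.2 ± 0.058 CPM, at least 565-fold higher against a floor of 3 counts over the group. FAM83A rose at least 432-fold and SIGLEC1 at least 311-fold on the same floor. Against that floor the order differs, with SLC28A3 above FAM83A, and TDRD9 and RASD2 above SIGLEC1, genes singled out after their values were seen. CACNA1I, which encodes a T-type calcium channel subunit, had 1 count in vehicle and 2127 counts with DB2115, a ratio of 1975 with a 95% counting interval of 354 to 78030. H19, an imprinted long non-coding RNA on chromosome 11, rose from 0.089 ± 0.045 to 138 ± 6.49 CPM (log2 fold change 10.51, edgeR adjusted p = 3.29e-13). It had 7 counts in vehicle and 11380 with DB2115, a ratio of 1509 (732 to 3755). The mitochondrial valine transfer RNA gene MT-TV had 3 counts in vehicle and 2964 with DB2115, a ratio of 917 (314 to 4450). It lies directly between the ribosomal RNA genes MT-RNR1 and MT-RNR2, so its reads cannot be assigned to the transfer RNA with certainty. The counting intervals cover counting error only. The floors are less strict than such intervals, whose lower 95% limits were 459 for KRT80, 351 for FAM83A and 252 for SIGLEC1. The vehicle counts of CACNA1I and MT-TV lay in vehicle library B alone, and the fitted log2 fold changes were 9.88 and 8.88 without vehicle library A and 12.98 and 13.45 without library B, while that of H19 was 11.15 without library B.

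The 6 largest falls were those of RGS18, TASL, DDN, SEMA3A, POLR3G and MYC. RGS18 had 807 counts in vehicle and 3 with DB2115, a ratio of 0.00345 (95% counting interval 0.00071 to 0.0101). Those 3 counts lay in DB2115 library B alone, and the fitted log2 fold change was -11.69 without that library and -7.14 without DB2115 library A. TASL, an adaptor in endolysosomal Toll-like receptor signalling, fell from 63.5 ± 1.77 to 1.57 ± 0.305 CPM, a log2 fold change of -5.34 (edgeR adjusted p = 3.16e-12). Its ratio was 0.02464 (95% counting interval 0.02052 to 0.02935). DDN fell with a log2 fold change of -4.89 and SEMA3A, a secreted semaphorin, with one of -4.81. POLR3G, a subunit of RNA polymerase III, went from 28.9 ± 0.15 to 1.03 ± 0.163 CPM. MYC (chromosome 8, 127735434 to 127741434) fell with a log2 fold change of -4.66 (SE 0.10, adjusted p = 2.16e-12, edgeR quasi-likelihood), 25.4-fold lower.

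The SPI1 transcript itself stood at 182 ± 7.2 CPM in vehicle and 191 ± 27.1 CPM with DB2115 (n = 2 each). SPI1 lies on chromosome 11, 47354860 to 47378576, on the minus strand. Its log2 fold change was 0.06 (SE 0.08, adjusted p = 0.526, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), so no change was called. The estimate depended on which DB2115 library was kept, being 0.19 (adjusted p = 0.0219) without DB2115 library B and -0.11 (adjusted p = 0.244) without DB2115 library A.

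**Figure D1:**
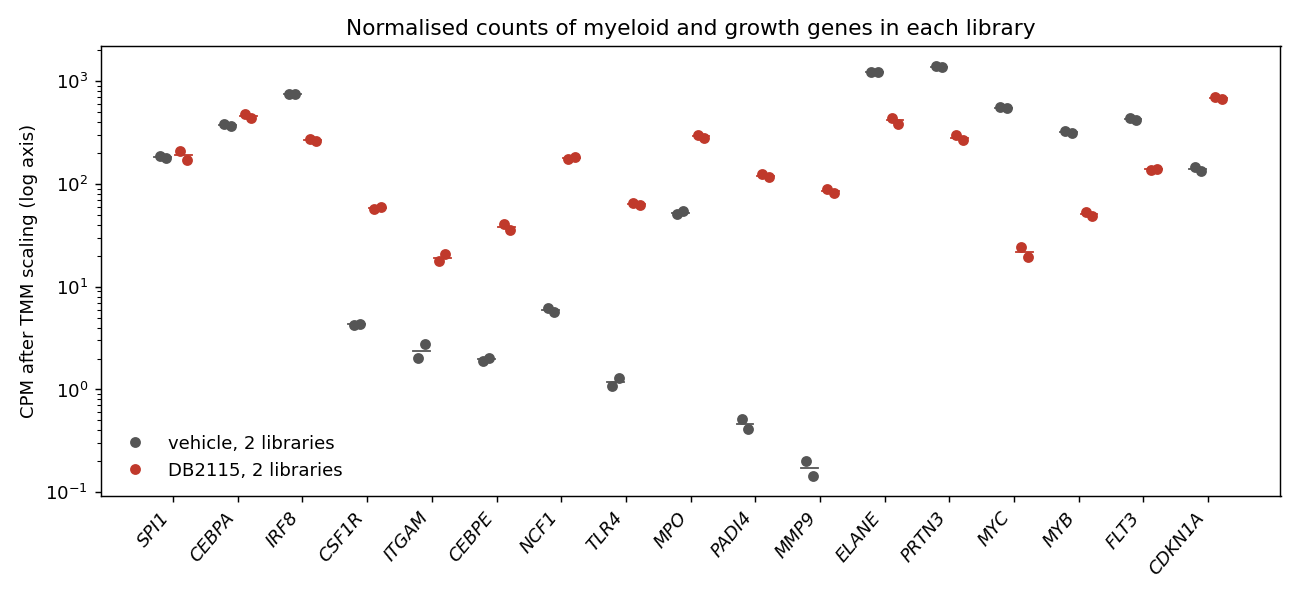
Normalised counts (CPM after TMM scaling, log axis) of 17 myeloid and growth genes, with 1 point per library and a line at the mean of the 2 vehicle (grey) or 2 DB2115 (red) libraries. SPI1 overlaps between the groups, whereas CSF1R, ITGAM, CEBPE, TLR4, PADI4 and MMP9 lie higher and MYC, MYB, ELANE and PRTN3 lower in both DB2115 libraries.

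Genes known as PU.1 targets in myeloid cells were mostly higher with DB2115. Of 38 tested, 29 rose and 6 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 1.20. That median was 0.649 after the trend of fold change with transcript GC content and length was removed. CSF1R, the receptor for macrophage colony-stimulating factor, rose 13.6-fold from 4.29 ± 0.066 to 58.2 ± 1.43 CPM (log2 fold change 3.76, SE 0.09, adjusted p = 5.59e-12). ITGAM, the integrin CD11b, rose 7.92-fold, TLR4, the lipopolysaccharide receptor, 52.7-fold, and FGR, a Src-family kinase, 34.6-fold. NCF1, a subunit of the phagocyte NADPH oxidase, rose 30.4-fold, but it shares near-identical sequence with pseudogene copies and its value is uncertain. The members that fell were BTK, CSF2RA, CTSS, ELANE, FCGR1A and LYZ. Against all other tested genes the list was higher by camera with a preset correlation (adjusted p = 3.14e-14), a call lost at adjusted p = 0.394 with an estimated correlation. None of the 17 list calls held with an estimated correlation. In that setting the test also rests on 2 residual degrees of freedom, so a lost call cannot be put down to correlation among genes. The type I interferon list lost its call too, although its estimated correlation, -0.0113, lay below the preset 0.01.

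Monocyte and macrophage markers mostly rose alongside. Of 19 tested, 14 rose and 2 fell, also when adjusted over the list alone, and the median log2 fold change was 3.76. Another 9 of the 28 listed were too low to test. A marker silent in vehicle could enter only by rising, which tilts these values upward. CD86, a co-stimulatory ligand, rose from 0.421 ± 0.193 to 27.9 ± 1.52 CPM, and ITGAX, the integrin CD11c, from 2.76 ± 0.129 to 47.1 ± 1.07 CPM. VCAN, TREM2, VSIG4 and CD14 rose as well, whereas the scavenger receptor CD36 (-2.31) and the Fc receptor FCGR1A (-0.48) fell. The list was higher by camera (adjusted p = 4.2e-08), against adjusted p = 0.394 with an estimated correlation. Its median was 3.01 without vehicle library B (adjusted p = 1.67e-05), 2.99 without a filter on low counts (adjusted p = 9.67e-07) and 1.07 when 1 CPM in 3 libraries was required (adjusted p = 0.000644), each still called. It shares 5 genes with the PU.1 target list.

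Neutrophil and granulocyte genes moved in both directions, with more members higher. Of 20 tested, 11 rose and 6 fell, the same counts as adjusted over the list alone, with a median log2 fold change of 1.38. That median was 0.82 after the trend of fold change with transcript GC content and length was removed. MMP9, the gelatinase of late granules, rose from 0.172 ± 0.038 to 85.3 ± 6.28 CPM, and PADI4, a peptidylarginine deiminase of mature neutrophils, from 0.462 ± 0.071 to 120 ± 6.33 CPM. CEBPE, the transcription factor of terminal granulocyte differentiation, rose 19.4-fold to 38.4 ± 3.58 CPM, and S100A8 and S100A9 had log2 fold changes of 1.61 and 2.34. CAMP and MMP8, genes of secondary granules, had no count in vehicle and rose at least 96.2-fold and at least 92.5-fold, to 3.78 and 3.63 CPM. Of the 29 listed members, 9 were too low to test and 3 were not called. LTF, LCN2, CEACAM8, OLFM4 and PGLYRP1 were among these untested or uncalled members. A member silent in vehicle could enter the test only by rising, which tilts the list upward. The azurophil granule genes ELANE (-1.57), PRTN3 (-2.28), AZU1 (-1.40) and CTSG (-1.03) fell, with GFI1 (-0.98) and FUT4 (-1.67), whereas MPO, a myeloperoxidase of the same granules, rose 5.52-fold. The list was higher by camera (adjusted p = 0.00261), with adjusted p = 0.478 with an estimated correlation. That call was also lost without vehicle library B (adjusted p = 0.0749) and with all 6 columns, which counts the pooled column as a library (adjusted p = 0.208), and its median turned to -0.23 (adjusted p = 0.969) when 1 CPM in 3 libraries was required.

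Myeloid transcription factors moved in both directions. Of 27 tested, 10 rose and 8 fell, also when adjusted over the list alone, and the list was not called (median log2 fold change 0.11, camera adjusted p = 0.941). ETS1 (2.60), JUN (2.44), ID2 (2.29) and CEBPB (1.15) were among those that rose. EGR1 (-3.26), MYB (-2.65), ELF1 (-1.67) and IRF8 (-1.49) were among those that fell.

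The genes associated with the MLL-AF9 fusion programme also separated. Of 25 tested, 12 fell and 8 rose, the same when adjusted over the list alone. MYB, a transcription factor of progenitor growth, fell from 319 ± 8.37 to 50.8 ± 3.36 CPM, FLT3, the receptor kinase mutated in this line, from 431 ± 12.8 to 139 ± 1.63 CPM, and ZEB2 from 194 ± 9.61 to 64.2 ± 3.27 CPM. CDK6 (-1.19), MEF2C (-1.28) and BCL2 (-0.94) fell too, whereas HOXA9 (0.40), HOXA10 (0.87) and MEIS1 (0.71) rose. The list was lower by camera (median log2 fold change -0.14, adjusted p = 0.0117), against adjusted p = 0.394 with an estimated correlation and 0.208 with all 6 columns. The median shrank to -0.05 with upper-quartile factors (adjusted p = 0.0174) or total counts (adjusted p = 0.0198), to -0.08 without a filter on low counts (adjusted p = 0.0382) and to -0.06 when 1 CPM in 3 libraries was required (adjusted p = 0.0461).

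MYC targets and ribosome biogenesis genes fell without exception. All 30 tested members fell, also when adjusted over the list alone, 28 of them at least 2-fold, and the median log2 fold change was -1.66. DDX21, a nucleolar helicase, went from 1172 ± 6.68 to 287 ± 11 CPM, and BOP1, a factor of large-subunit assembly, from 423 ± 5.44 to 105 ± 4.18 CPM. The camera test gave adjusted p = 6.13e-34, and adjusted p = 0.394 with an estimated correlation. Cytosolic ribosomal protein genes fell less. Of 34 tested, 28 fell and none rose, or 31 adjusted over the list alone, with a median log2 fold change of -0.29. RPL35 (-0.61), RPL19 (-0.50) and RPL6 (-0.49) had the smallest adjusted p. The list call had adjusted p = 0.0171, and adjusted p = 0.811 with an estimated correlation. The call was also lost when 1 CPM in 3 libraries was required (adjusted p = 0.1), and fry, which tests a list against no change and not against other genes, gave adjusted p = 0.0717.

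Genes of DNA replication were mostly lower, and those of mitosis mostly higher. Of 33 S-phase genes, 22 fell and 3 rose, also when adjusted over the list alone (median log2 fold change -0.34, camera adjusted p = 0.0154, and adjusted p = 0.619 with an estimated correlation). That call was lost at adjusted p = 0.0938 when 1 CPM in 3 libraries was required. The replicative helicase subunits MCM6 (-1.15) and MCM4 (-0.92) and the initiation factor MCM10 (-0.89) had the smallest adjusted p among those that fell, whereas TK1 (0.92), CDT1 (0.31) and PRIM1 (0.28) rose. Of 32 genes of G2 and mitosis, 20 rose and 5 fell, or 21 and 5 adjusted over the list alone, but the list was not called (median 0.32, adjusted p = 0.183). It was called higher without a filter on low counts (adjusted p = 0.00523), and fry, against no change, gave adjusted p = 0.032. The call with all 6 columns (adjusted p = 0.0123) counts the pooled column as a library and adds no independent evidence. HMMR (1.14) and MKI67 (0.69) rose, whereas KIF20A (-2.30) and PLK1 (-0.46) fell. The replication-dependent histone genes all lay below 5 CPM. Of 17 tested, 4 rose and 2 fell, or 1 and 1 adjusted over the list alone (adjusted p = 0.933 for the list).

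p53 target genes and apoptosis regulators were mostly higher. Of 27 p53 targets, 19 rose and 4 fell, also when adjusted over the list alone (median log2 fold change 0.55, camera adjusted p = 4.22e-05, and adjusted p = 0.394 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 4.86-fold from 140 ± 9.50 to 680 ± 21.5 CPM, BTG2, an antiproliferative factor, 13-fold and TP53INP1 12.1-fold, whereas MDM2 (0.18) and BAX (0.27) rose little. Of 24 apoptosis regulators, 17 rose and 4 fell, the same adjusted over the list alone (median 0.55, adjusted p = 0.0115, and adjusted p = 0.689 with an estimated correlation). The pro-apoptotic BH3-only gene BMF rose from 18.2 ± 0.166 to 286 ± 11.1 CPM. CFLAR (1.15), an inhibitor of caspase-8 activation, also rose, whereas BCL2 (-0.94) and PMAIP1 (-0.90) fell.

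Lysosome genes were mostly higher and genes of the ATF4 and unfolded protein responses mostly lower. Of 33 lysosome genes, 25 rose and 5 fell, also when adjusted over the list alone (median log2 fold change 0.67, camera adjusted p = 0.000412, and adjusted p = 0.46 with an estimated correlation). The protease CTSB rose 2.50-fold, the sialidase NEU1 2.63-fold and TFEB, the transcription factor of lysosome biogenesis, 2.31-fold. Of 29 genes of the ATF4 and unfolded protein responses, 23 fell and 4 rose, the same adjusted over the list alone (median -0.56, adjusted p = 2.62e-05, and adjusted p = 0.478 with an estimated correlation). The amino acid transporters SLC7A5 (-2.08) and SLC7A11 (-2.48) and the serine synthesis enzyme PSAT1 (-1.75) fell, while GDF15 (4.55) rose.

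Interferon-stimulated and inflammatory genes were mostly higher. Of 28 type I interferon response genes, 18 rose and 5 fell, also when adjusted over the list alone (median log2 fold change 1.03, camera adjusted p = 0.0171, and adjusted p = 0.394 with an estimated correlation). OAS3 rose from 2.15 ± 0.060 to 24.9 ± 2.37 CPM, IFIT3 from 0.973 ± 0.074 to 11.5 ± 0.077 CPM and STAT2 2.26-fold, whereas USP18 (-0.81) fell. The list call was lost when 1 CPM in 3 libraries was required (median 0.53, adjusted p = 0.1). Of 22 inflammatory and NF-kB genes, 17 rose and 4 fell, the same adjusted over the list alone (median 1.54, adjusted p = 0.00158, and adjusted p = 0.394 with an estimated correlation). TNF rose from 7.06 ± 0.120 to 40.2 ± 6.0 CPM, PTGS2 9.26-fold and TNFAIP2 3.16-fold, while NFKB1 (-0.87) and TNFAIP3 (-0.90) fell. With that filter the median of this list was 0.71 (adjusted p = 0.0493), and without a filter on low counts it was 2.28 (adjusted p = 0.000103).

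Metabolic, stress and antigen-presentation lists were either lower or not called. Nuclear oxidative phosphorylation genes fell in 24 of 32 cases and rose in 2, or 24 and 3 adjusted over the list alone (median log2 fold change -0.35, camera adjusted p = 0.0171, and adjusted p = 0.772 with an estimated correlation), with COX7A2 (-0.64), SDHB (-0.56) and UQCRQ (-0.73) having the smallest adjusted p. The call was lost when 1 CPM in 3 libraries was required (adjusted p = 0.1), and fry gave adjusted p = 0.0533 against no change. Among 29 hypoxia and glycolysis genes 16 fell and 5 rose, or 17 and 5 adjusted over the list alone (median -0.20, adjusted p = 0.146), with HK2 (-2.38) and LDHA (-1.20) lower and HK1 (1.18) higher. That list was called lower without DB2115 library B (median -0.53, adjusted p = 0.00174) and without a filter on low counts (median -0.20, adjusted p = 0.00452). Sterol biosynthesis genes rose in 8 and fell in 9 of 24 cases, or 9 and 10 adjusted over the list alone (adjusted p = 0.61). Genes of the NRF2 response rose in 8 and fell in 7 of 21, also when adjusted over the list alone (adjusted p = 0.926), with HMOX1 (5.61) and NQO1 (1.73) higher and TXNRD1 (-0.96) lower. Of 11 MHC class II genes 4 rose, HLA-DMA (3.61) and HLA-DMB (5.32) among them, and 2 fell, the same adjusted over the list alone (adjusted p = 0.55, and 0.0454 by fry against no change).

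**Figure D2:**
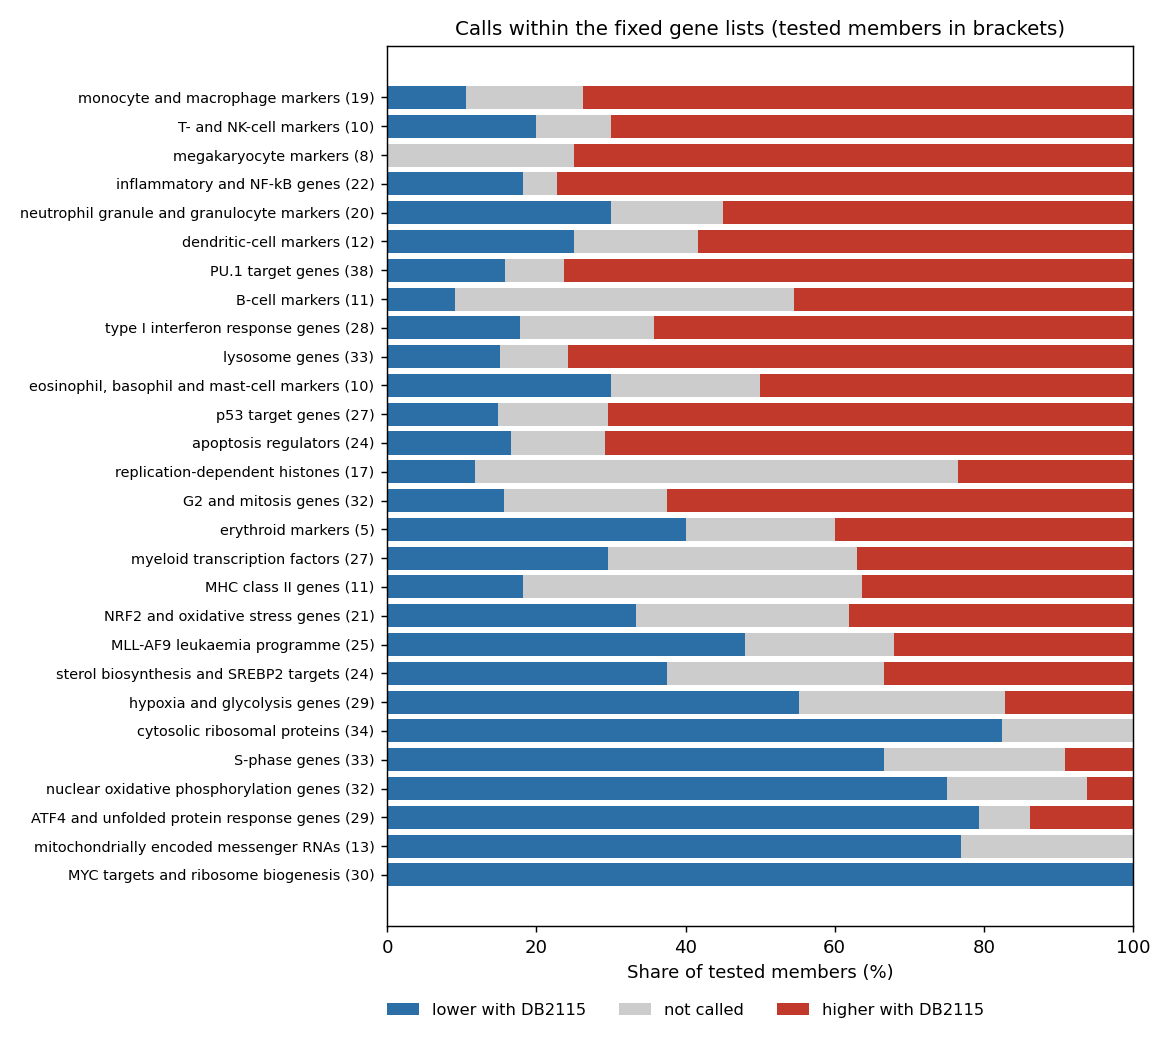
Share of tested members of each of the 28 fixed gene lists (percent, horizontal axis; number tested in brackets) that were higher (red), lower (blue) or not called (grey) with DB2115, ordered by median log2 fold change. Monocyte and macrophage markers are at the top and the 30 MYC and ribosome biogenesis genes, all lower, at the bottom.

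Markers of other blood lineages were mostly near the detection floor in vehicle, and several rose. Low counts left 9 of 17 megakaryocyte, 13 of 23 T- and NK-cell, 8 of 19 B-cell and 19 of 24 erythroid markers untested. The same held for 6 of 18 dendritic-cell and 10 of 20 eosinophil, basophil and mast-cell markers. A marker silent in vehicle passed the filter only if it rose, so counts and calls of these lists are tilted upward. Of 8 megakaryocyte markers 6 rose and none fell, also when adjusted over the list alone (median log2 fold change 1.86, camera adjusted p = 0.0234, and adjusted p = 0.394 with an estimated correlation), and only 1 of them reached 5 CPM in vehicle. The call was lost when 1 CPM in 3 libraries was required (adjusted p = 0.0758, with 3 genes left). The median was 2.55 without vehicle library B (adjusted p = 0.0121), 2.48 without a filter on low counts (adjusted p = 0.0027) and 2.47 with all 6 columns (adjusted p = 0.0194). NFE2 rose from 43.1 ± 3.18 to 101 ± 5.94 CPM and GP9 5.63-fold, while ITGA2B had 3 counts in vehicle and 486 with DB2115, a ratio of 150 (51.2 to 732). The vehicle counts of ITGA2B all lay in library A, and its fitted log2 fold change was 10.92 without vehicle library A and 6.04 without library B. Of 10 T- and NK-cell markers 7 rose and 2 fell, the same adjusted over the list alone (median 2.35, adjusted p = 0.022, and adjusted p = 0.394 with an estimated correlation). The cytotoxic granule genes PRF1, 30.5-fold, and NKG7, 4.36-fold, rose, GNLY had 1 count in vehicle and 196 with DB2115, a ratio of 182 (32.3 to 7223), and NCAM1 (-1.11) fell. The count of GNLY in vehicle also lay in library A, with a fitted log2 fold change of 9.62 without vehicle library A and 6.21 without library B. The call of the T- and NK-cell list was lost with all 6 columns (adjusted p = 0.0762), and the median was 1.38 when 1 CPM in 3 libraries was required (adjusted p = 0.0282). B-cell markers rose in 5 and fell in 1 of 11 cases (adjusted p = 0.238, and 0.00423 by fry against no change), with CD79A (3.35) higher and PAX5 (-2.17) lower. Dendritic-cell markers rose in 7 and fell in 3 of 12 (adjusted p = 0.429, and 0.00131 by fry), CD209 (4.05) among the higher. Eosinophil, basophil and mast-cell markers rose in 5 and fell in 3 of 10 (adjusted p = 0.941). Erythroid markers rose in 2 and fell in 2 of 5 (adjusted p = 0.266, and 0.00366 by fry), TFRC (-1.72) being the most abundant, and their median of 0.13 was above 0 although camera placed the list lower. It was -0.91 when 1 CPM in 3 libraries was required, with 3 genes left, and 1.20 without a filter on low counts. The counts for these last 4 lists were the same adjusted over the list alone.

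Mitochondrially encoded RNAs changed by class. Messenger RNAs made up 4.71% ± 0.465 of all counts in vehicle and 3.26% ± 0.331 with DB2115 (SD, n = 2), whereas the share of mitochondrial ribosomal RNAs went from 0.514% ± 0.044 to 3.92% ± 0.173. Of the 13 messenger RNAs 10 fell and none rose, also when adjusted over the list alone, with a median log2 fold change of -0.78. MT-ATP6 (-1.03), MT-ATP8 (-0.97) and MT-ND4L (-0.92) fell, while MT-ND1 (0.10, adjusted p = 0.378), MT-ND2 (0.01, adjusted p = 0.938) and MT-ND3 (-0.05, adjusted p = 0.664) were not called. The 12S ribosomal RNA MT-RNR1 rose from 406 to 16947 CPM (log2 fold change 5.38, SE 0.09) and the 16S ribosomal RNA MT-RNR2 from 4910 to 21048 CPM (2.10, SE 0.09). Of 21 mitochondrial transfer RNA genes tested 19 rose and none fell, with a median of 2.05. Their vehicle levels ran from 0.036 CPM for MT-TV to 306 CPM for MT-TN. These short genes adjoin or lie close to ribosomal and messenger RNA genes, so their reads cannot be assigned to mature transfer RNAs with certainty. The messenger RNA list was lower by camera (adjusted p = 0.0134), and had adjusted p = 0.707 with an estimated correlation. The call was also lost when 1 CPM in 3 libraries was required (adjusted p = 0.064), and fry gave adjusted p = 0.0568 against no change. The difference in messenger RNA share, -1.45 percentage points, had an exact two-sided permutation p = 0.333, the smallest that 2 against 2 libraries allow, and with all mitochondrial genes counted the difference was 2.02 points in the other direction.

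**Figure D3:**
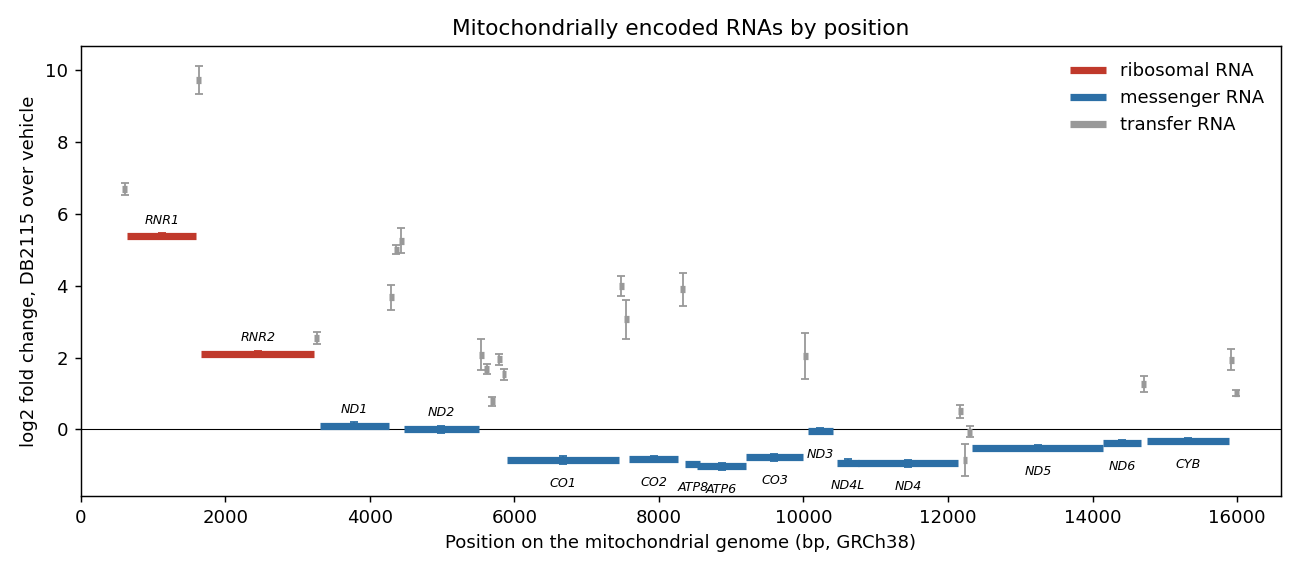
Log2 fold change (DB2115 over vehicle, vertical axis) of mitochondrially encoded ribosomal (red), messenger (blue) and transfer (grey) RNAs by position on the mitochondrial genome (bp, GRCh38), with bars of 1 standard error and horizontal bars spanning each gene. MT-RNR1 (5.38) and MT-RNR2 (2.10) lie above 0, and the 10 called messenger RNAs lie below it. For transfer RNAs with very few vehicle counts, such as MT-TV with 3, the error bars are shorter than counting error.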

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

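The 6-column fit, the fit without mitochondrial genes and the block on column letters were chosen after seeing the data. The 64 genes selected by the naming rule other than SPI1 kept their direction and their side of the threshold in 878 of 878 comparisons with an alternative. Most were picked from these same data for large or clear changes, so this outcome was largely built in. Fits that removed a gene, by a filter or with the mitochondrial genes, give no comparison for it. Between 8838 and 10709 genes were called when 1 library was left out, and between 4189 and 4647 of them changed at least 2-fold. A lone library was then assumed to vary like those of the other group. DESeq2 called 9892 genes, limma-voom 11068 and the 6-column fit 13838. Requiring 1 CPM in 3 libraries left 2540 genes changed at least 2-fold and 10 called lists, and turned the neutrophil and granulocyte list to a median of -0.23. That filter removes genes silent in 1 group by construction. No list was called with an estimated correlation (0 of 28, against 19 by fry, which tests against no change and not against other genes, and 17 in the main test). Both that estimate and the test made with it rest on 2 residual degrees of freedom, so the losses cannot be put down to correlation among genes. Of 335 list results under the other alternatives 320 were the same, 10 lost and 4 gained a call and 1 reversed. The SPI1 estimate ranged from -0.11 to 0.19 without 1 library, with a call (0.19, adjusted p = 0.0219) without DB2115 library B, and the cause was not tested. The mitochondrial share of counts ran from -1.78 to -1.12 points without 1 library, and was 2.02 points with all mitochondrial genes counted, because ribosomal RNA then outweighs messenger RNA. The columns carry letters and no replicate numbers, so the planned block could not be matched to the labels. A replicate block on the column letters, which are not stated to pair libraries, leaves 1 residual degree of freedom and called 11424 genes, 4608 of them changed at least 2-fold, and 17 lists, with a log2 fold change of 0.06 for SPI1. The differences of library A from B were barely related between the groups (Pearson r = 0.0337 across genes). Low counts limit the size of the rise for genes silent in vehicle, which is given as a bound.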

Other observations

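In this part, the tests on whole mitochondrial content, heavy-strand position, sequencing depth, poly(A) selection as the whole cause and the GC trend as the whole cause, at either correlation, were chosen after the result was seen. A set of 116 genes with at most 3 counts in vehicle reached at least 1 CPM in both DB2115 libraries, and 97 of these are protein coding. The reverse, at most 3 counts with DB2115 and at least 1 CPM in both vehicle libraries, held for 4 genes: RGS18, CD180, TMEM156 and GABRG1. The gained genes included CHIT1, the macrophage chitotriosidase, with 1 count in vehicle and 360 with DB2115, and the chemokine CCL24, with 2 and 724 counts. They also included genes of other tissues, such as CYP19A1 (3 and 690 counts), the aromatase of steroid synthesis, and the skeletal muscle genes RYR1 (0 and 566), MYH1 (0 and 369) and TNNC2 (1 and 321).

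Transcripts rich in G and C were more often higher. Across 13008 protein-coding genes, which are not independent replicates, the Spearman correlation of log2 fold change with transcript GC content was 0.279. In the fifth of genes with the lowest GC content (median 40.0%) 20.0% rose and 52.0% fell, and in the highest (median 62.2%) 51.1% rose and 23.9% fell. The hypothesis that longer genes fell and shorter genes rose was not borne out, with a correlation of -0.0116 between fold change and genomic length.

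The gained genes may reflect transcription or background reads. Background from genomic DNA should raise silent genes alike, but CPM summed over 381 olfactory receptor genes had a ratio of 1.34 (95% interval 1.18 to 1.54, for counting error only), where a rise above 4-fold had been expected of such background. Sequencing depth was also close, with a ratio of total counts of 1.01. Both values argue against these technical sources, and a response to DB2115 remains a hypothesis, since the pattern was found and tested on the same data.

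The rise of mitochondrial ribosomal RNA might come from a selection step that let more RNA without a poly(A) tail through. The test set before the result was seen left this open, because the median log2 fold change of 21 nuclear RNAs that lack a tail was 0.466 but their upper quartile, 1.08, passed the bound of 1. Of the 21, 17 were replication-dependent histone genes, all below 5 CPM. S-phase genes were mostly lower with DB2115, so this set need not measure selection alone. As to the whole cause, RN7SL2, at 0.466 (SE 0.27), and the 5.8S ribosomal RNA genes, lower still, lay below MT-RNR2 at 2.10 (SE 0.09). The 5.8S genes were themselves called higher (edgeR adjusted p = 0.0122 to 0.0222). SNORD3A (1.70, SE 0.50) and H2AC6 (1.89, SE 0.36), both below 5 CPM, came nearer to MT-RNR2. The comparison assumes that DB2115 left the cells' own levels of these RNAs unchanged, which was not tested, so it cannot decide. A rise of mitochondrial content as a whole, with every class of its RNA higher, is argued against by the messenger RNAs (median -0.783). All mitochondrial genes together still went from 5.27% to 7.29% of counts, so the messenger RNAs speak only against a rise shared by all classes. Fold changes of 14 heavy-strand genes were related to distance from the promoter with Spearman's rho = -0.49 (permutation p = 0.0795). This missed the bounds that had been set for an effect of position. The 12 messenger RNAs alone gave rho = -0.189 (permutation p = 0.56). So few genes cannot exclude such an effect, which remains open.

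The GC trend could have raised the PU.1 target list. After the trend with GC content and length was removed, the list's median went from 1.20 to 0.649, which is 54.2% (95% bootstrap interval 18% to 111%), so how much of it follows the trend cannot be told apart. The granulocyte list kept 59.8% of its median (1.38 to 0.82), the monocyte and macrophage list 80.9% and the MYC and ribosome biogenesis list 108%. As the whole cause the trend is argued against, because the list still lay above other genes, with an unadjusted cameraPR p = 2.92e-07 at a preset correlation and p = 0.0253 at the estimated correlation of 0.168, against 0.0208 before the trend was removed. That evidence is weaker at the estimated correlation, where it rests on the unadjusted cameraPR p = 0.0253 and on a correlation estimated with 2 residual degrees of freedom. Camera on the counts then lost the call of this list (adjusted p = 0.394). That test also rests on 2 residual degrees of freedom, so its loss cannot decide the question. Whether the trend is technical also stays open: within groups, the ratio of the libraries followed GC content with rho = 0.175 for DB2115 and 0.00868 for vehicle. A GC bias shared by both DB2115 libraries would be confounded with the treatment.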
